A study of Homo sapiens with 12 samples.

How the data were processed

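RNA from 3 established human multiple myeloma cell lines was measured on 12 one-colour Agilent expression arrays. The lines were RPMI-8226 and MM.1S, each sampled at day 6, and KMS-12PE, sampled at day 12. Each line was treated with SGC0946, a small molecule inhibitor of the histone H3 methyltransferase DOT1L, or with the solvent DMSO. There were 2 arrays in each of the 6 groups. The dose of SGC0946 is not given in the sources used here. Per the labels' protocols, cells grew in serum-containing RPMI medium, total RNA was purified on columns, and Cy3-labelled material was made with a low-input one-colour kit. The labels do not say that the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which can be technical.

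Per the submitters' processing notes, the scans were read with Agilent Feature Extraction 10.7. The value used is the processed green signal, a linear intensity that per the file headers is background-subtracted and detrended, spatially and multiplicatively, with a small substitute value for spots not above background. Probe coordinates are those in the scanner files, on human genome build hg19 per the file headers. The deposited series table was compared with each array's scanner intensity. It holds the same processed signal rounded to 3 digits, with a largest difference of 0.497%, so its scale is linear, it is not centred, and it carries no direction. Its column medians lay between 5.23 and 13.3 in units of intensity. It was used as an alternative.

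Each array held 62976 spots, of which 4259 control spots were left out. The other 58717 spots carried 50599 probes, 902 of them printed on more than 1 spot. Spots flagged as outliers, 249 to 407 per array, were left out, and the other spots of a probe were averaged. Gene names were updated through the RefSeq table supplied with the data. By accession 28174 probes were named, 2618 carried a current symbol, 620 were renamed through a unique synonym and 19187 kept the name in the file. This gave 36400 gene features, 20371 with a symbol and 16029 with a placeholder name. Of these, 9536 had more than 1 probe, and the probe with the highest mean over the 12 arrays stood for the gene. Probes with a value on all 12 arrays went before others in this choice. A gene with a missing value on any array was not fitted. For DOT1L in RPMI-8226, 1 of the 3 detected probes went the other way, by 0.07 on the log2 scale. Detected probes also disagreed in direction for ATF3 in RPMI-8226 and MLLT6 in MM.1S.

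From the deposited processed signal its log2 value was taken here, minus each array's 75th percentile of it. Percentiles of the processed signal ran from 111.6 to 338.1, and 36.9% to 47.1% of probes were well above background per array. No spot was saturated (0 on each array). The number of arrays limits the precision. A gene was tested in a line where its probe was well above background on both arrays of at least 1 of the line's groups. All tests of single genes used lmFit and eBayes in limma 3.58.1 (R 4.3.3, with jsonlite 2.0.0 and the package data.table, version 1.17.8). One model of the 6 group means was fitted over the 12 arrays, with 6 residual degrees of freedom, a prior of 1.54 degrees of freedom and a prior variance of 0.0125. The groups share one estimate of the spread, so a gene's spread in a line where it is at background enters its test in another line. There were 7 contrasts: SGC0946 minus DMSO in each line, the mean of the 3 effects, and the differences of effects between pairs of lines. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene is called at an adjusted p under 0.05.

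Genes not well above background in a group have only a bound there, printed as "at least N-fold". It sets the mean normalized log2 value of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest signal among probes well above background and the probe's own signal. The adjusted p beside it is that of the fit. Where 1 of the 2 arrays of a group measured a gene, this is stated.

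For gene groups, 26 lists with 726 genes were written, of which 718 were on the array. The list of DOT1L partners holds DOT1L itself, and that of MYC targets holds MYC. The plasma cell identity list holds IRF4, PRDM1, XBP1 and KLF2, so their calls count in it too. They were tested with camera in limma at a preset correlation of 0.01, with adjustment over the 78 tests of 26 lists in 3 lines. Camera with an estimated correlation and fry were run beside it. Called members of a list were also counted after Benjamini-Hochberg adjustment over the list alone. The lists, the contrasts, the filter, the alternatives other than those named as added, and the rule for named genes were fixed before the data were examined.

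The rule named DOT1L, IRF4, MYC, PRDM1, XBP1, KLF2 and CDKN1A in every line. It named the 6 largest rises and 6 largest falls per line among called genes with a symbol whose treated arrays both lay beyond both controls and whose higher group was well above background on both arrays. It named the 2 called genes with the smallest adjusted p in each list with at least 3 called members, the 8 genes called in the same direction in all 3 lines with the smallest largest adjusted p, and the 3 genes with the smallest adjusted p for a difference between each pair of lines. A few genes that the rule takes are not reported here. Any other gene is named because its list held few called members, or because it moved against the rest of its list, and was chosen after its values were seen.

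Each line lay on a slide of its own with both of its groups, scanned on its own, so 3 slides and 3 scans coincide with the 3 lines, and KMS-12PE differs also in day. Slide as a block therefore adds nothing within a line and was not run. Within a slide the treatment follows the array's place on the slide.

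The scripts were tested on simulated data with the real signal levels. At 2-fold, 83% of 100 changed genes were recovered in the RPMI-8226 comparison of 17125 genes, 74% of 50 in the MM.1S comparison of 15128 genes and 78% of 50 in the KMS-12PE comparison of 17127 genes. At 1.5-fold these shares were 62%, 60% and 64%. For differences of 2-fold between lines they were 50% for RPMI-8226 against MM.1S, over 14235 genes, and 56% for RPMI-8226 against KMS-12PE, over 15238 genes. False calls made up at most 4.58% of the calls. A gene's simulated noise had the same spread in every group. These shares therefore do not cover the wider spread between the treated MM.1S arrays.

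Alternatives were normexp background correction with offset 50, quantile normalization, centring on probes well above background on all 12 arrays (15947 probes), the series table, no filter on dim probes, a stricter filter, the mean of all probes of a gene, eBayes with trend and robust settings, the replicate number as a block, only the arrays of the lines compared, a 2-fold minimum, and leaving out each array. The 75th percentile over those detected probes was added after the share of probes well above background had been seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.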

Results

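Gene expression was compared between myeloma cells treated with the DOT1L inhibitor SGC0946 and cells given DMSO, in the RPMI-8226 and MM.1S lines at day 6 and in KMS-12PE at day 12. Multiple myeloma is a cancer of antibody-secreting plasma cells, and DOT1L is a histone H3 methyltransferase that acts on transcribed genes. The series title gives the question as whether inhibition of DOT1L blocks proliferation through IRF4 and MYC. Each line contributed 2 treated and 2 control arrays, and each value is a log2 ratio of SGC0946 to DMSO unless stated otherwise. The 75th percentile of the processed signal was 309.9 to 338.1 on the RPMI-8226 control arrays and 287.4 to 333.7 on the treated arrays. It was 158.8 to 193.2 and 111.6 to 210.5 in MM.1S, and 247.9 to 260.5 and 291.5 to 312.3 in KMS-12PE. Between 36.9% and 47.1% of probes were well above background per array.

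The arrays separated first by cell line, with 54.5% of the variance on the first principal component and 36.2% on the second. The third component, with 4.5%, was positive on all DMSO arrays and negative on all SGC0946 arrays. The SD of a gene between arrays of a group was 0.106 for control and 0.114 for treated RPMI-8226, 0.126 and 0.223 for MM.1S, and 0.0861 and 0.118 for KMS-12PE. The treated MM.1S arrays thus lay further apart than those of the other groups. In every group the arrays differed by more than repeated spots of one array allowed, for example by 0.046 against an expected 0.0182 in control RPMI-8226, so no pair was treated as 1 array given a second time. The labels list each array as a sample of its own and it was counted as a replicate, although this spread does not show that the cultures were separate. All 73 called genes named in RPMI-8226, 72 in MM.1S and 63 in KMS-12PE had both treated arrays beyond both control arrays. Chance alone gives this for 33.3% of unselected genes with 2 arrays per group. The named genes were called on the same arrays, which favours it, and the rule for the largest changes requires it.

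IRF4, the transcription factor that maintains plasma cell identity, fell in all 3 lines. It fell by 1.02 in RPMI-8226 (SE 0.0619, adjusted p = 4.52e-05), by 1.11 in MM.1S (adjusted p = 4.62e-05) and by 0.68 in KMS-12PE (adjusted p = 0.000536). MYC, the growth-driving transcription factor, fell by 0.68 in RPMI-8226 (SE 0.0577, adjusted p = 0.000182) and by 0.50 in KMS-12PE (adjusted p = 0.00158). In MM.1S MYC fell by 0.26 (adjusted p = 0.0108), a call that ended under 8 of 23 alternative settings, including without the second control array (adjusted p = 0.0572), and turned to 0.02 (adjusted p = 0.82) under quantile normalization. KLF2, a zinc finger factor of B and plasma cells, fell by 1.10, 1.47 and 0.54 in RPMI-8226, MM.1S and KMS-12PE (adjusted p = 0.000145, 5.39e-05 and 0.00666). PRDM1, which encodes the plasma cell factor BLIMP-1, fell by 0.72, 0.87 and 0.33 (adjusted p = 0.000825, 0.000377 and 0.0361), and the call in KMS-12PE ended under 13 of 23 settings, among them the loss of any 1 RPMI-8226 or KMS-12PE array (adjusted p 0.0616 to 0.165). XBP1, the transcription factor of the secretory pathway, fell by 0.38, 0.58 and 0.67 (adjusted p = 0.00796, 0.00111 and 0.00125). Its call in RPMI-8226 ended without a filter on dim probes (adjusted p = 0.0589) and without the second treated array (adjusted p = 0.054), and under normexp its calls in MM.1S and KMS-12PE ended (adjusted p = 0.0684 and 0.223). In KMS-12PE the calls of IRF4, MYC and KLF2 also ended under normexp (adjusted p = 0.169, 0.549 and 0.305). Their log2 ratios were still -0.622, -0.445 and -0.466 there, and those of XBP1 were -0.675 in MM.1S and -0.594 in KMS-12PE. The KLF2 call in KMS-12PE also ended without the second control array, at -0.523.

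The transcript of DOT1L itself fell by 0.68, 0.51 and 0.59 in the same order of lines (adjusted p = 0.00477, 0.012 and 0.015). Of the 3 detected DOT1L probes in RPMI-8226, 1 gave 0.07, against the direction of the others. These calls ended under 4 settings in MM.1S, including without the first control array (adjusted p = 0.0658), and 7 in KMS-12PE, including without any 1 of its 4 arrays (adjusted p 0.0604 to 0.0944). CDKN1A, the cell cycle inhibitor p21, gave 0.38 in RPMI-8226 (SE 0.448, adjusted p = 0.577). In MM.1S CDKN1A was at least 1.33-fold lower (adjusted p = 0.0405), and that call ended under 16 of 22 settings, 9 of them the loss of 1 array (adjusted p 0.0584 to 0.145). CDKN1A was not well above background on both arrays of either KMS-12PE group and was not tested there. On hg19 the probe of IRF4 lies on chromosome 6 from 411002 to 411061, that of MYC on chromosome 8 from 128753268 to 128753327, and that of KLF2 on chromosome 19 from 16438246 to 16438305. The PRDM1 probe lies on chromosome 6 from 106557662 to 106557721, the XBP1 probe on chromosome 22 from 29190733 to 29190792, and the DOT1L probe on chromosome 19 from 2227105 to 2229821. Exon annotation of the probes was not used here.

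**Figure D1:**
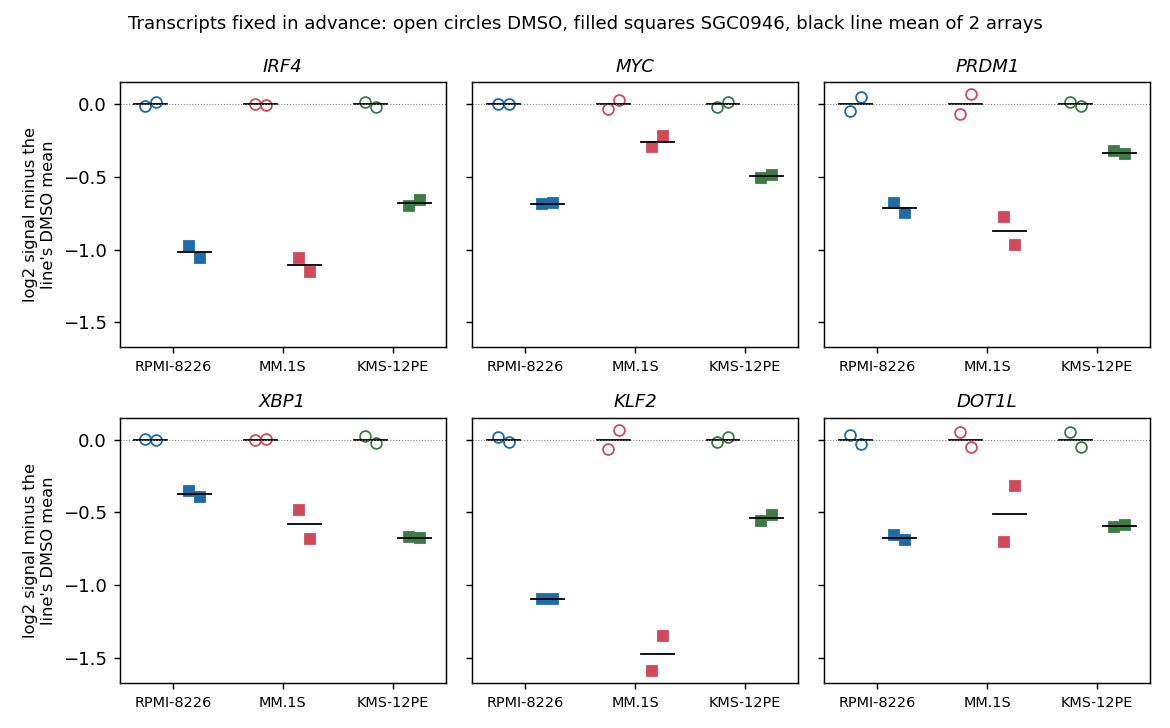
Log2 signal of IRF4, MYC, PRDM1, XBP1, KLF2 and DOT1L on each array, minus the mean of the DMSO arrays of the same line, with open circles for DMSO, filled squares for SGC0946 and a black line at the mean of the 2 arrays. All treated means lie under the DMSO mean, from -1.47 for KLF2 in MM.1S to -0.26 for MYC in MM.1S, and the latter turns to 0.02 under quantile normalization.

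In RPMI-8226, the lists of interferon-stimulated, MHC class II and NF-kB target genes rose with SGC0946, and those of cholesterol synthesis, MYC target and plasma cell genes fell. The interferon-induced chemokine CXCL9 rose 23.7-fold (log2 4.57, SE 0.122, adjusted p = 9.88e-07). CXCL8, which attracts neutrophils, was at least 14.4-fold higher (adjusted p = 3.98e-05), and CD180, a Toll-like receptor homologue of B cells, at least 10.96-fold higher (adjusted p = 2.64e-05). FN3K, a kinase that acts on glycated proteins, was at least 11.04-fold lower (adjusted p = 0.000578), and the lanosterol synthase LSS fell by 1.24 (SE 0.0783, adjusted p = 5.16e-05). In total 4905 of 17125 genes tested were called, 2151 higher and 2754 lower, of which 749 rose and 474 fell at least 2-fold.

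Among the other large changes in RPMI-8226, NEURL1B, a ubiquitin ligase, was at least 9.73-fold higher (adjusted p = 4.46e-07), the collagenase MMP13 at least 6.59-fold and the lectin-like CLECL1 at least 5.01-fold higher. Called falls were at least 7.20-fold for the noncoding PRINS, 3.50-fold for ASAP1-IT1, 2.83-fold for KRTAP26-1 and 2.80-fold for TMEM14EP. NLRP13 was at least 2.32-fold lower, a bound of 1.46-fold without the first and 3.70-fold without the second control array, and its fitted change turned to 0.04 under normexp.

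Interferon-stimulated genes rose in 27 of 43 measured members, and the other 16 did not pass the test (camera adjusted p = 1.24e-13). IFI44 was at least 4.32-fold and OAS3, which senses double-stranded RNA, at least 4.65-fold higher. Of 16 genes of MHC class II, which presents antigen to helper T cells, 11 rose and 1 fell (adjusted p = 1.12e-08), with HLA-DRA up by 3.92 (SE 0.0859) and HLA-DMB up by 3.28 (SE 0.105). The list of MHC class I presentation had 10 of 21 members higher and 1 lower (adjusted p = 0.00105), with HLA-F at 0.58 and B2M at 0.53, and the direction of this list turned under normexp. NF-kB targets rose in 15 of 26 members and fell in 3 (adjusted p = 6.78e-07), with the monocyte attractant CCL2 at 3.32 (SE 0.0747). CCL3 was at least 3.97-fold higher, while ICAM1, CFLAR and SOD2 fell. Adjusted over the list alone, 27 interferon-stimulated, 11 MHC class II, 11 MHC class I and 16 NF-kB members were higher, and 2 MHC class II, 2 MHC class I and 3 NF-kB members lower.

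Lists of other cell types and of other B cell stages moved in the same arrays. Myeloid markers rose in 6 of 10 measured members (adjusted p = 0.000164), with the endotoxin co-receptor CD14 at 2.25 (SE 0.0668) and the growth factor receptor CSF1R at 3.57 (SE 0.277). The T and NK cell list had 3 of 9 members higher (adjusted p = 0.0357, or adjusted p = 0.107 with an estimated correlation), and its call ended under normexp, quantile normalization and the added scaling, and without the first (adjusted p = 0.0934) or the second treated MM.1S array (adjusted p = 0.088). Of these, the T cell adhesion molecule CD2 was at least 8.97-fold higher and the cytotoxic protease GZMB rose by 1.51. Stromal and epithelial markers rose in 4 of 7 members (adjusted p = 0.0197, or adjusted p = 0.124 with an estimated correlation), including DCN at 1.96 and CDH1 at 2.09, the latter detected on 1 of 2 control arrays. That call ended under normexp and without the first control array (adjusted p = 0.112). Of 15 mature B cell genes 8 rose and 3 fell (adjusted p = 0.00865, or adjusted p = 0.107 with an estimated correlation), with the MHC class II activator CIITA at 2.17 and SPIB at 1.99. The 4 called HOXA and MEIS members of 8 measured rose (adjusted p = 0.00475, or adjusted p = 0.0604 with an estimated correlation): MEF2C at 1.89, PBX3 at 1.41, HOXA5 and HOXA13. Adhesion and homing genes rose in 10 of 21 members and fell in 3 (adjusted p = 0.00234, or adjusted p = 0.0509 with an estimated correlation), with the chemokine receptors CCR2 at 2.66 and CCR7 at least 3.54-fold higher, and this call ended under normexp. With p-values adjusted over the list alone, 6 myeloid, 3 T and NK cell, 4 stromal, 8 mature B cell, 4 HOXA and MEIS and 11 adhesion genes were higher, and 4 mature B cell and 4 adhesion genes lower.

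Cholesterol synthesis genes fell in 20 of 23 members in RPMI-8226 and rose in 1 (adjusted p = 2.9e-09), with DHCR7 down by 0.79 beside LSS. MYC targets fell in 19 of 50 members (adjusted p = 3.04e-07), including UTP20, a ribosome assembly factor, by 0.63. IRF4 and plasma cell identity genes fell in 15 of 26 (adjusted p = 0.000412), including the immunoglobulin assembly factor MZB1 by 0.72, while CD38 and PIM2 rose. The unfolded protein response and ER list had 15 of 34 members lower (adjusted p = 0.000164), with the signal peptidase subunit SPCS3 down by 0.54 and SDF2L1 by 0.48. Glycolysis and hypoxia genes fell in 10 of 27 (adjusted p = 0.0013), with NDRG1 down by 0.96 and the kinase PDK1 by 0.76. G2/M and mitosis genes rose in 10 of 50 members and fell in 2 (adjusted p = 0.0197, or adjusted p = 0.0685 with an estimated correlation), with the topoisomerase TOP2A at 0.54 and the kinesin KIF20A at 0.37. The direction of that list turned under normexp. Its mean less that of all genes, 0.0732, became -0.0387 without the first treated array (adjusted p = 0.0967) and 0.00908 without the second (adjusted p = 0.0559), and the call ended without either. Lower genes adjusted over the list alone were 21 for cholesterol synthesis, 24 for MYC targets, 15 for plasma cell identity, 21 for the unfolded protein response and 12 for glycolysis, and for G2/M 10 were higher and 1 lower.

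The remaining lists did not pass the set test in RPMI-8226. S phase genes were higher in 3 and lower in 13 of 46 (adjusted p = 0.124), including the replication factor CDC45 at -0.58 and cyclin CCNE2 at 0.66. CDK inhibitors and p53 targets were higher in 8 and lower in 4 of 28 (adjusted p = 0.0586), with SESN1 at 1.18 and CDKN2D at 1.11. The BCL2 family had 5 of 19 members higher and 3 lower (adjusted p = 0.579), with the survival factor BCL2L1 at -1.003 and the death-promoting BMF at 0.63. ATF4 targets split into 5 higher and 9 lower of 31 (adjusted p = 0.508), with the arginine transporter SLC7A1 at -0.54 and the stress factor NUPR1 at least 9.99-fold higher. The mean of that list was above 0 and its test pointed down, and the BCL2 family's median was below 0 and its test pointed up. DOT1L and its partners were lower in 5 of 19 (adjusted p = 0.0656), with ELL2 at -0.70 and KMT2A at -0.49. Heat shock and immediate early genes were higher in 3 and lower in 2 of 21 (adjusted p = 0.821), with JUN at 0.70 and ATF3 at 0.54, a gene with 1 of 4 probes in the other direction. Translocation and cyclin D genes were higher in 1 and lower in 4 of 12 (adjusted p = 0.302), with NSD2 at -0.46. In limma 0 of 23 replication-dependent histone genes (2 at an unadjusted p under 0.05), 0 of 45 ribosomal protein genes (0 unadjusted) and 0 of 6 erythroid markers (1 unadjusted) were called, with set test adjusted p = 0.14, 0.766 and 0.634. Counts adjusted over the list alone differed for the BCL2 family (6 higher, 6 lower), ATF4 targets (6 and 10) and translocation genes (1 and 5), and were the same in the other lists of this group. Median and test also differed in sign for heat shock genes. The median of the histone list turned from 0.10 to -0.16 under normexp, and medians also changed sign for erythroid markers under quantile normalization and for the BCL2 family and ribosomal proteins under the added scaling.

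Of the calls in RPMI-8226, 43.9% were higher, and 56.3% (2647 of them higher and 2056 lower) with the 75th percentile taken over detected probes. Without the second control array 3034 genes were called, without the second treated array 3207, and under normexp 1795.

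In MM.1S, the lists of interferon-stimulated, NF-kB target and mature B cell genes rose with SGC0946, and those of S phase, cholesterol synthesis, MYC target and unfolded protein response genes fell. CXCL13, a chemokine that attracts B cells, was at least 26.8-fold higher (adjusted p = 1.26e-06), the ubiquitin-like UBD at least 21.9-fold (adjusted p = 0.00029) and BCL6, the germinal centre repressor, at least 12.0-fold (adjusted p = 0.000102). ANKRD37, a hypoxia-responsive gene, fell 4.55-fold (log2 -2.19, SE 0.0928, adjusted p = 1.37e-05), and PLAAT2, a phospholipid-modifying enzyme, fell 5.34-fold (log2 -2.42, SE 0.0945, adjusted p = 9.54e-06). In total 6030 of 15128 genes were called, 2185 higher and 3845 lower, of which 606 rose and 194 fell at least 2-fold. With the spread taken from the MM.1S arrays alone, 2158 were called. GPR171 was at least 7.65-fold and CXCL9 at least 4.73-fold higher. The long noncoding OLMALINC fell 4.09-fold, and SNORA15 and STARD8 were at least 2.01-fold and 1.33-fold lower. RASL12 was at least 3.14-fold lower, a bound of 6.77-fold without the first and 1.45-fold without the second control array, and its call ended for 9 of the 12 arrays when 1 was left out (adjusted p 0.0539 to 0.184).

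Interferon-stimulated genes rose in 24 and fell in 6 of 40 measured members in MM.1S (adjusted p = 4.3e-08), with IFITM3 at 1.73 (SE 0.0924) and MX1 at 1.29 (SE 0.0727), both antiviral factors. The 6 that fell were ISG20, BST2, SAMD9L, OAS2, HERC5 and EIF2AK2. MHC class II genes rose in 10 and fell in 1 of 15 (adjusted p = 1.11e-05, or adjusted p = 0.0572 with an estimated correlation), with HLA-DMB at 2.02 and HLA-DRB1 at 2.01. NF-kB targets rose in 8 of 25 (adjusted p = 0.00209), with CCL2 at 3.39 (SE 0.0747) and the interferon-induced CXCL10 at 2.28, while SOD2, CCL3 and CCL5 fell. Mature B cell genes rose in 7 and fell in 1 of 13 (adjusted p = 0.0013), with SPIB at 0.98 beside BCL6. CDK inhibitors and p53 targets rose in 7 and fell in 4 of 28 (adjusted p = 0.00373, or adjusted p = 0.107 with an estimated correlation), with CDKN1C at 1.29 and BBC3 at 0.79, and the 4 lower were PPM1D, PMAIP1, CDKN1A and MDM2. Adjusted over the list alone, 25 interferon-stimulated, 10 MHC class II, 8 NF-kB, 8 mature B cell and 7 CDK inhibitor and p53 members were higher, and 6, 1, 3, 1 and 4 of these lists, in this order, lower.

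A few small lists passed the set test in MM.1S less firmly. The BCL2 family had 6 members higher and 4 lower of 17 (adjusted p = 0.0441, or adjusted p = 0.327 with an estimated correlation), with the death-promoting BMF at 2.13 (SE 0.0804) and BBC3 higher. BCL2L11, BIK and the survival genes BCL2A1 and MCL1 also rose, and BCL2L12, HRK, BID and PMAIP1 fell. Myeloid markers had 3 of 7 members higher and 1 lower (adjusted p = 0.0466, or adjusted p = 0.134 with an estimated correlation), with AIF1 at least 5.92-fold higher and CD33 at 1.33. CD14 gave -0.27, was detected on 1 of 2 treated arrays, turned to 0.05 under normexp and was not called without the second control array (adjusted p = 0.0811). Of 3 stromal and epithelial markers KRT18 and EPCAM rose (adjusted p = 0.0476, or adjusted p = 0.133 with an estimated correlation). Leaving out single arrays ended the BCL2 call for 7 arrays (adjusted p 0.0502 to 0.159), the myeloid call for 4 (0.0518 to 0.475) and the stromal call for 8 (0.0502 to 0.48), with the mean of the stromal list less that of all genes at -0.114 without the first control array. The BCL2 call also ended under normexp, the myeloid call under quantile normalization and both scalings on detected probes, and the stromal call under normexp and all of these. When adjusted over the list alone, the counts of these lists were the same.

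S phase and DNA replication genes fell in 41 of 46 members in MM.1S (adjusted p = 1.14e-10), with the checkpoint mediator CLSPN down by 1.27 (SE 0.101). Replication-dependent histones fell in 22 of 24 (adjusted p = 3.04e-07, or adjusted p = 0.292 with an estimated correlation), with H2AC4 and H3C4 each down by 0.85. G2/M genes fell in 19 and rose in 2 of 50 (adjusted p = 0.00156), with CKS2 down by 0.58 and the proliferation marker MKI67 by 0.47, and this call ended under quantile normalization (adjusted p = 0.209). Cholesterol synthesis genes fell in 20 of 23 (adjusted p = 1.07e-09), with the epoxidase SQLE down by 1.35 (SE 0.0724) and DHCR7 by 1.16 (SE 0.063). MYC targets fell in 38 of 50 (adjusted p = 2.79e-08), with LDHA, the lactate dehydrogenase, down by 0.81 and the serine-glycine enzyme SHMT2 by 0.66. Glycolysis and hypoxia genes fell in 18 and rose in 1 of 25 (adjusted p = 4.93e-05), with PDK1 down by 1.48. Lower genes adjusted over the list alone were 42 for S phase, 22 for histones, 19 for G2/M, 20 for cholesterol synthesis, 39 for MYC targets and 19 for glycolysis.

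Plasma cell identity genes fell in 14 and rose in 1, FCRL5, of 28 in MM.1S (adjusted p = 0.000412). The unfolded protein response and ER list had 22 of 34 members lower (adjusted p = 8.08e-07), with SPCS3 down by 0.87 and SDF2L1 by 0.81. ATF4 and amino acid response genes fell in 18 and rose in 2 of 30 (adjusted p = 0.0013, or adjusted p = 0.131 with an estimated correlation), with SLC7A1 down by 0.73 and the mTORC1 inhibitor DDIT4 up by 0.82. Ribosomal protein genes fell in 23 of 45 (adjusted p = 0.000164, or adjusted p = 0.457 with an estimated correlation), with RPSA down by 0.38 and RPS3 by 0.30. Under quantile normalization that call ended (adjusted p = 0.852), the mean of the list less that of all genes was -0.00783, and the set test pointed up. For plasma cell identity 14 genes, for the unfolded protein response 23, for ATF4 19 and for ribosomal proteins 27 were lower when adjusted over the list alone.

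The other lists did not pass in MM.1S. MHC class I presentation had 2 members higher and 8 lower of 21 (adjusted p = 0.363), with the ER chaperone CANX at -0.96 and PSME2 at -0.54, and its median changed sign under quantile normalization and the added scaling. The T and NK cell list had 2 higher and 1 lower of 4 (adjusted p = 0.401), with CD2 at 2.01 and CD4 at -0.56. Adhesion and homing genes were higher in 5 and lower in 4 of 22 (adjusted p = 0.137), with CCR2 at 1.40 and CCR10 at -0.94. Of 6 HOXA and MEIS genes 1 was higher (adjusted p = 0.261). DOT1L partners were higher in 4 and lower in 8 of 19 (adjusted p = 0.612), with ELL at -0.64 and MLLT6 at 0.57, a gene whose probes disagreed in direction. Heat shock genes were higher in 6 and lower in 8 of 22 (adjusted p = 0.766), with DUSP1 at 1.14 and FOSB at least 2.61-fold higher. Translocation and cyclin D genes were higher in 3 and lower in 5 of 12 (adjusted p = 0.744), with CX3CR1 at 3.35. In limma 0 of 4 erythroid markers were called (1 at an unadjusted p under 0.05, set test adjusted p = 0.381). Counts adjusted over the list alone differed for heat shock genes (8 higher, 9 lower) and were the same in the other lists of this group. The medians of the heat shock and translocation lists also changed sign under quantile normalization and the added scaling. Median and test differed in sign for these lists, and the mean of the DOT1L partners was below 0 while its median and test pointed up.

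Of the calls in MM.1S, 36.2% were higher, against 55.6% with only the MM.1S arrays in the fit (1199 higher, 959 lower). This share was 52.5% under normexp (292 higher, 264 lower), 46.8% under quantile normalization (2529 and 2870), 49.3% with the median of detected probes (2684 and 2764) and 61.6% with their 75th percentile (3223 and 2013), a scaling that moved the median of all genes by 0.137.

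In KMS-12PE, sampled at day 12, the lists of interferon-stimulated, MHC class II and NF-kB target genes rose with SGC0946, and those of MYC target, plasma cell and unfolded protein response genes fell. CCR7, the receptor that guides lymphocytes to lymph nodes, was at least 124-fold higher (adjusted p = 3.38e-06), the adhesion receptor ADGRG1 at least 11.8-fold and the chemokine CXCL10 at least 4.53-fold higher (adjusted p = 1.64e-06). Genes of the TRIM49 family on chromosome 11 fell, TRIM49 by 5.44-fold, TRIM49D1 by 6.06-fold and TRIM49B by at least 5.66-fold (adjusted p = 0.00261). In total 2766 of 17127 genes were called, 1279 higher and 1487 lower, of which 429 rose and 98 fell at least 2-fold. MYT1 was at least 5.75-fold, LHFPL2 at least 4.87-fold and the calcium-binding CALB2 at least 4.74-fold higher. The CALB2 call ended for 6 of the 12 arrays when 1 was left out (adjusted p 0.0524 to 0.137), and that of TRIM53AP for the first and the second control array (adjusted p = 0.0635 and 0.0772). The pseudogene GRM5P1 fell 6.66-fold (log2 -2.74, SE 0.285), SRSF3P2 was at least 2.66-fold and TRIM53AP at least 2.36-fold lower, and whether the related TRIM probes also bind each other's transcripts was open.

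Interferon-stimulated genes rose in 19 and fell in 1, ISG20, of 35 in KMS-12PE (adjusted p = 2.78e-13), with IFIT5 at 1.87 (SE 0.083) and MX1 at 1.73 (SE 0.0727). MHC class II genes rose in 11 and fell in 1 of 17 (adjusted p = 2.1e-10), with HLA-DRA at 1.54 and HLA-DRB1 at 1.42. MHC class I presentation genes rose in 6 and fell in 2 of 21 (adjusted p = 0.00805, or adjusted p = 0.0532 with an estimated correlation), with the immunoproteasome subunits PSMB8 at 1.06 and PSMB9 at 0.62. NF-kB targets rose in 5 and fell in 3 of 24 (adjusted p = 0.00436), with the T cell attractant CCL5 at 2.01, while CFLAR, ICAM1 and SOD2 fell. In the T and NK cell list CD2 at 1.92, CD3G at 2.74, CD96, LCK and ZAP70 rose, 5 of 12 members (adjusted p = 0.000279, or adjusted p = 0.0647 with an estimated correlation). CDK inhibitors and p53 targets rose in 8 and fell in 2 of 26 (adjusted p = 0.000396, or adjusted p = 0.06 with an estimated correlation), with TP53INP1 at 1.01 and BBC3 at 0.80, and CDKN2A and FAS lower. G2/M genes rose in 6 and fell in 2 of 50 (adjusted p = 0.00234), with KIF20A at 0.44 and TOP2A at 0.42. Adjusted over the list alone, 21 interferon-stimulated, 14 MHC class II, 10 MHC class I, 6 NF-kB, 6 T and NK cell, 8 CDK inhibitor and p53 and 6 G2/M members were higher, and 2, 1, 3, 4 and 2 were lower in the interferon, MHC class II, MHC class I, NF-kB and CDK inhibitor lists.

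Plasma cell identity genes fell in 10 and rose in 2 of 25 in KMS-12PE (adjusted p = 0.000969), with DERL3 and the costimulatory receptor CD28 higher, the latter by 3.19 and detected on 1 of 2 control arrays. MYC targets fell in 14 of 50 (adjusted p = 2.93e-06), with the polyamine enzyme ODC1 down by 0.93. The unfolded protein response and ER list had 12 members lower and 1 higher of 34 (adjusted p = 0.000279), with HERPUD1 down by 0.55. Cholesterol synthesis genes fell in 7 of 24 (adjusted p = 0.000395, or adjusted p = 0.14 with an estimated correlation), with SQLE down by 0.48 and DHCR7 by 0.44. Glycolysis and hypoxia genes fell in 9 and rose in 2 of 28 (adjusted p = 0.0156, or adjusted p = 0.06 with an estimated correlation), with ANKRD37 down by 1.82 and PDK1 by 1.30. Ribosomal protein genes fell in 3 of 45 (adjusted p = 0.0013, or adjusted p = 0.513 with an estimated correlation), RPL24 by 0.27 and RPL5 by 0.25 among them, calls that each ended for 10 of the 12 arrays when 1 was left out (adjusted p 0.0555 to 0.20 and 0.0511 to 0.18). That list's direction turned under quantile normalization, and its call ended under normexp (adjusted p = 0.0691). The histone list passed upward (adjusted p = 0.036, or adjusted p = 0.633 with an estimated correlation), although limma called 0 of its 24 members (1 at an unadjusted p under 0.05), and the call ended without the first treated array (adjusted p = 0.13). When adjusted over the list alone, 13 plasma cell, 16 MYC target, 14 unfolded protein response, 13 cholesterol, 11 glycolysis and 0 ribosomal genes were lower (12 ribosomal genes at an unadjusted p under 0.05 in limma).

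The last group of lists did not pass in KMS-12PE. S phase genes were lower in 2 of 46 (adjusted p = 0.145), and the median of the list changed sign under the added scaling. Mature B cell genes were higher in 2 of 8 (adjusted p = 0.0767) and stromal markers in 1 of 6, CDH1 (adjusted p = 0.161). Myeloid markers were higher in 2 and lower in 1 of 6 (adjusted p = 0.503), with CSF3R at 0.68 and CD14 at -0.44. Adhesion and homing genes were higher in 5 and lower in 5 of 19 (adjusted p = 0.452), with CCR1 at 2.25 and ITGB7 at 0.73. HOXA and MEIS genes were higher in 1 and lower in 3 of 11 (adjusted p = 0.161), with PBX3 at -1.01 and MEF2C at -0.30, a call that ended for 3 of the arrays when 1 was left out (adjusted p 0.0643 to 0.097). The BCL2 family was higher in 4 and lower in 3 of 20 (adjusted p = 0.332), with BMF at 1.20. ATF4 targets were higher in 4 and lower in 6 of 29 (adjusted p = 0.159), with ATF3 at 1.71 and DDIT4 at 0.79. DOT1L partners were higher in 2 and lower in 6 of 19 (adjusted p = 0.159), with MLLT10 at -0.58 and MLLT3 at -0.57. Heat shock genes were higher in 4 and lower in 2 of 19 (adjusted p = 0.766), with JUN at 0.93, and translocation genes higher in 2 and lower in 1 of 10 (adjusted p = 0.283). In limma 0 of 6 erythroid markers were called (0 at an unadjusted p under 0.05, set test adjusted p = 0.54). Counts adjusted over the list alone were 1 lower for S phase, 2 higher for stromal markers, 1 higher and 5 lower for HOXA and MEIS, 5 and 4 for the BCL2 family, 4 and 7 for ATF4 targets and 4 and 5 for heat shock, and the same in the other lists of this group. Median and test differed in sign for the adhesion, BCL2, translocation, myeloid and heat shock lists. Medians changed sign for the BCL2 and translocation lists under normexp, quantile normalization and both scalings on detected probes, for myeloid markers under the latter and for stromal markers under normexp.

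Of the calls in KMS-12PE, 46.2% were higher, against 77.9% under normexp (141 higher, 40 lower), 58.3% under quantile normalization (1376 and 985) and 64.4% with the 75th percentile of detected probes (1615 and 891). Without the first or second control array 1267 and 1143 genes were called, without the first or second treated array 1297 and 1217, and without the first or second treated MM.1S array 4473 and 4502.

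Across the lines, the mean of the 3 effects asked which genes moved on average. Here 6601 of 13493 genes were called, 2117 higher and 4484 lower, of which 203 rose and 26 fell at least 2-fold. Of these calls 32.1% were higher, against 42.2% under quantile normalization (2488 higher, 3410 lower) and 56.1% with the 75th percentile of detected probes (3161 and 2470). SGK1, a glucocorticoid-induced kinase, rose by 2.35 on average (SE 0.0345, adjusted p = 1.13e-07), with 3.49, 1.24 and 2.32 in RPMI-8226, MM.1S and KMS-12PE. ALOX5AP, which serves leukotriene synthesis, rose by 3.21, 1.46 and 2.30, the prostaglandin receptor PTGER4 by 1.38, 1.51 and 1.93, and HLA-DRB1 by 1.98, 2.01 and 1.42. CHRNA6, a nicotinic receptor subunit, was at least 14.4-fold higher in RPMI-8226 and rose by 2.17 and 1.16 in the other lines. CXCL10 rose by 2.19 in RPMI-8226 and 2.28 in MM.1S. SMIM14 rose by 2.27, 1.00 and 1.91, with 1 of 2 RPMI-8226 control arrays above background. The mean effect was -0.93 for IRF4 (SE 0.0358, adjusted p = 3.62e-06), -0.48 for MYC, -1.04 for KLF2, -0.64 for PRDM1, -0.55 for XBP1 and -0.59 for DOT1L.

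Calls overlapped between lines, which share no control arrays. RPMI-8226 and MM.1S shared 797 genes called higher, against 246.7 for independent lists, and 1126 called lower against 666.5, with 377 in opposite directions against 821.1. For RPMI-8226 and KMS-12PE there were 572 higher (126.5), 675 lower (235.1) and 163 opposite (345.6), and for MM.1S and KMS-12PE 485 higher (141.9), 830 lower (381.6) and 198 opposite (477.1). Over all 3 lines 308 genes were higher, against 15.6, and 468 lower, against 68.0. All calls come from 1 fit with a shared spread, so a gene of low spread tends to be called in several lines. The numbers for independent lists do not allow for this. On every slide the treated arrays also lay in higher-numbered rows than the control arrays. An effect of the array's place could thus be shared by the lines and cannot be told from the treatment. Shared falls may also depend on the scaling, with the median ratio of all genes below 0 in each line (-0.0545, -0.0992 and -0.075). Across genes, which are not independent replicates, the Pearson correlation of log2 ratios was 0.43, 0.401 and 0.402 for these pairs and the Spearman correlation 0.33, 0.341 and 0.352. Of the 78 list tests 48 passed, 27 upward and 21 downward, and 27 passed with an estimated correlation.

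**Figure D2:**
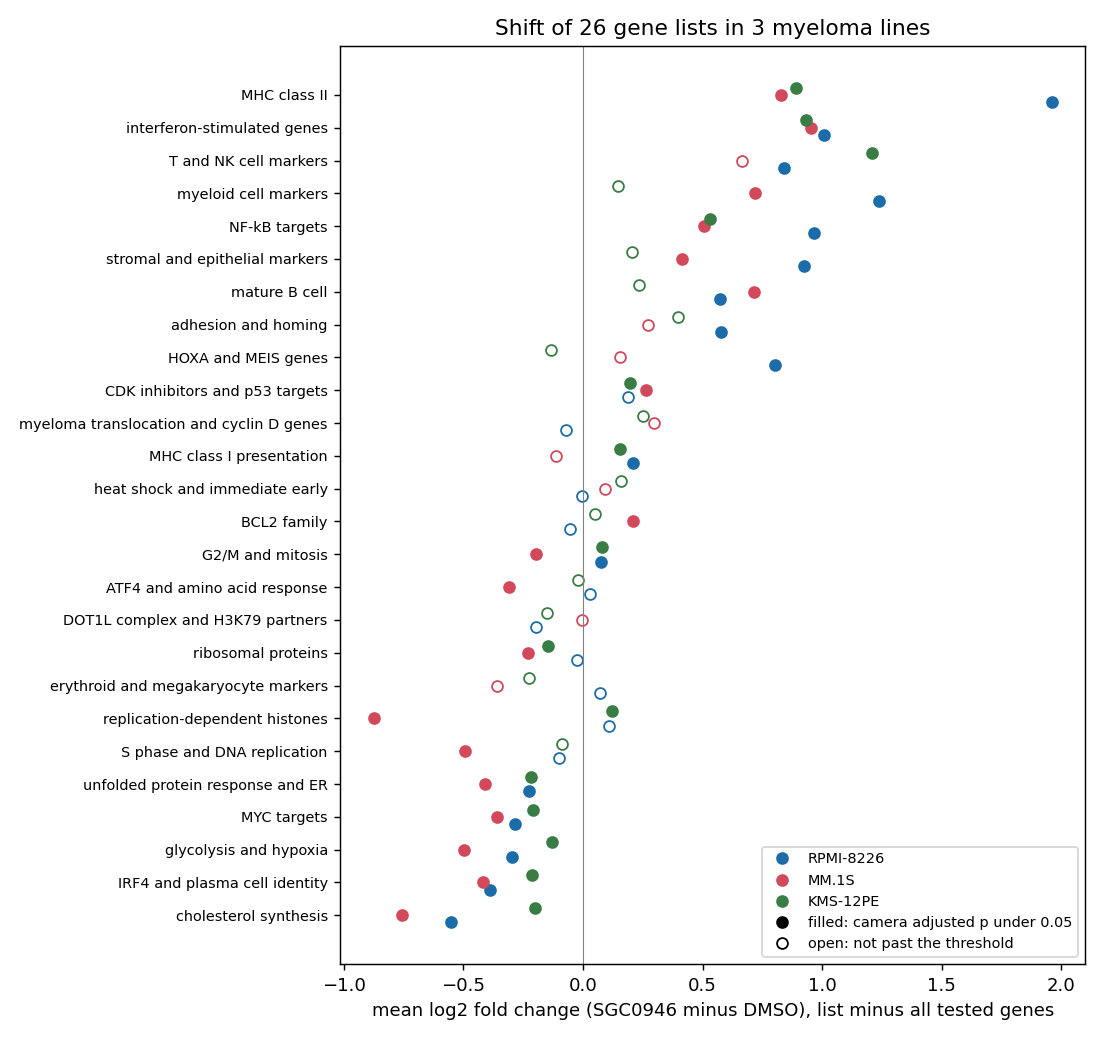
Mean log2 ratio of each of the 26 lists, SGC0946 minus DMSO, less that of all genes tested, per line, with filled points for a camera adjusted p under 0.05 and open points for the rest. Fitted values of genes below background in a group are included; 48 of the 78 points are filled, and of these MHC class I and G2/M in RPMI-8226 turn under normexp, while under quantile normalization ribosomal proteins turn in KMS-12PE and lie at -0.00783 in MM.1S.

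Effects differed between lines for 3279 of 14235 genes for RPMI-8226 against MM.1S (1838 with the higher ratio in RPMI-8226), 1692 of 15238 for RPMI-8226 against KMS-12PE (775 higher) and 2204 of 13870 for MM.1S against KMS-12PE (877 higher). These splits depended on the scaling. For RPMI-8226 against MM.1S the higher and lower genes numbered 1838 and 1441 as reported, 1473 and 1531 under quantile normalization, 1355 and 1697 with the median of detected probes, 1312 and 1715 with their 75th percentile, and 70 and 119 under normexp. For MM.1S against KMS-12PE 877 and 1327 became 1179 and 971 with the 75th percentile of detected probes. MARCKS, a substrate of protein kinase C, rose by 2.66 in RPMI-8226 and 0.41 in MM.1S (difference 2.24, adjusted p = 1.9e-05). CD14 rose by 2.25 in RPMI-8226 and fell by 0.44 in KMS-12PE (difference 2.69, adjusted p = 2.42e-05). COBLL1 fell by 0.24 in MM.1S and rose by 2.40 in KMS-12PE (difference -2.63, adjusted p = 2.47e-05). CCL3 rose in RPMI-8226 and fell by 0.34 in MM.1S (adjusted p = 1.4e-05 for the difference). BRINP2 fell by 0.75 in RPMI-8226 and was at least 2.55-fold higher in MM.1S (adjusted p = 1.4e-05). SPINT2, a protease inhibitor, gave -0.14 in RPMI-8226 (adjusted p = 0.177) and -0.18 in MM.1S (adjusted p = 0.0752) and was at least 1.88-fold higher in KMS-12PE, where LHFPL2 also rose. LHFPL2 gave 0.23 in RPMI-8226 (adjusted p = 0.0575) and 1.12 in MM.1S. Under normexp the calls for BRINP2, LHFPL2 and SPINT2 ended. Leaving out single arrays ended the calls within MM.1S of COBLL1 for 3 arrays (adjusted p 0.0516 to 0.101) and CCL3 for 2 (0.0593 and 0.0983). The fall of IRF4 was larger in MM.1S than in KMS-12PE (difference -0.43, adjusted p = 0.018), a call that ended under 9 of 23 settings, and it did not differ detectably between RPMI-8226 and MM.1S (difference 0.09, SE 0.0876, adjusted p = 0.498).

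The cell cycle lists were set against each other between lines with camera, a test added after they were seen to move apart. The S phase list differed between MM.1S and KMS-12PE by -0.38 (adjusted p = 1.97e-09, or adjusted p = 0.0677 with an estimated correlation) and between RPMI-8226 and MM.1S by 0.38 (adjusted p = 2.81e-07, or adjusted p = 0.0878 with an estimated correlation). Between RPMI-8226 and KMS-12PE the S phase difference was 0.00145 (adjusted p = 0.725). Histones differed by 0.999 between RPMI-8226 and MM.1S and by -0.999 between MM.1S and KMS-12PE (adjusted p = 1.44e-08 and 1.63e-09, or adjusted p = 0.366 for each with an estimated correlation). The G2/M list differed by 0.26 between RPMI-8226 and MM.1S and by -0.25 between MM.1S and KMS-12PE (adjusted p = 1.71e-05 and 1.74e-06, or adjusted p = 0.0677 for each with an estimated correlation). Cholesterol synthesis differed by -0.51 between MM.1S and KMS-12PE (adjusted p = 9.69e-09, or adjusted p = 0.118 with an estimated correlation). Interferon-stimulated genes gave adjusted p = 0.601, 0.666 and 0.817 over the 3 pairs.

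Line, slide and scan coincide, and KMS-12PE was sampled later, so differences between lines cannot be separated from these. Leaving out 1 RPMI-8226 array gave 1755 to 1927 genes for RPMI-8226 against MM.1S (1755 and 1776 without the control arrays, 1927 and 1827 without the treated ones), and 5365 came without the first treated MM.1S array. For RPMI-8226 against KMS-12PE the counts were 875 and 788 without the control and 951 and 812 without the treated RPMI-8226 arrays, 823 and 772 without the control and 886 and 790 without the treated KMS-12PE arrays, and 2889 and 2915 without the treated MM.1S arrays. For MM.1S against KMS-12PE they were 1447 and 1380 without the control MM.1S arrays, 4333 without the first treated one, 925 and 919 without the control and 1082 and 934 without the treated KMS-12PE arrays.

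**Figure D3:**
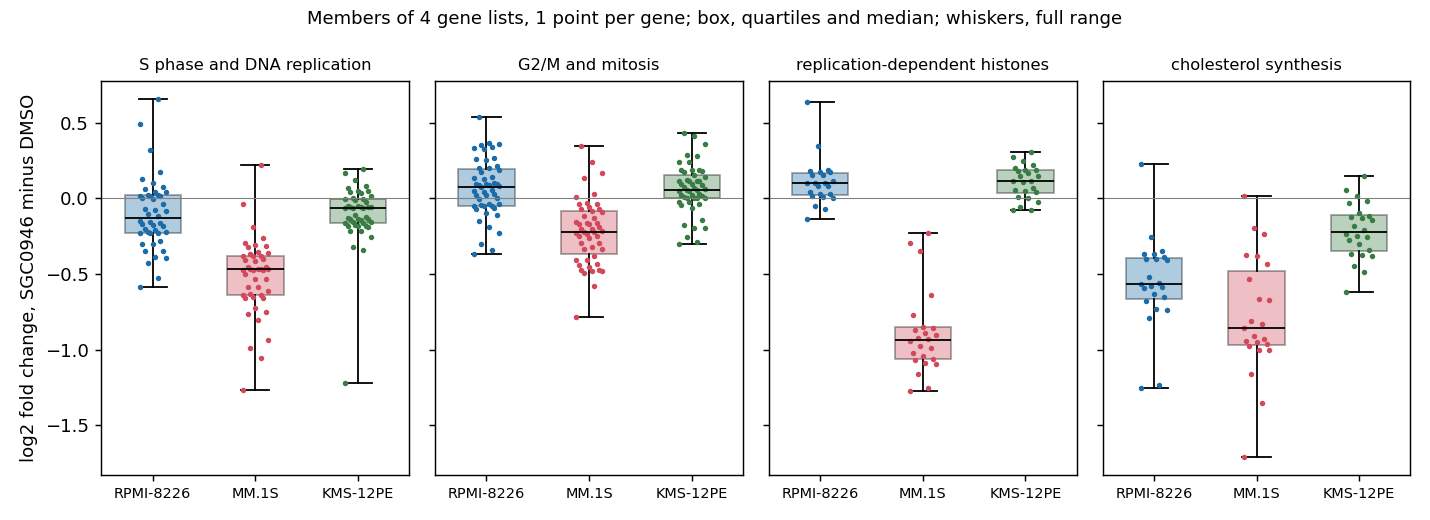
Log2 ratio of SGC0946 to DMSO for members of the S phase, G2/M, replication-dependent histone and cholesterol synthesis lists in each line, 1 point per gene, with boxes for the quartiles and median and whiskers over the full range. In MM.1S 41 of 46 S phase genes and 22 of 24 histone genes fell; the G2/M and histone medians in RPMI-8226 turn under normexp and the S phase median in KMS-12PE under the added scaling, and fitted values of genes below background in a group are included.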

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

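The search for base runs shared between TRIM probes and the distances along the third principal component were chosen only after the results had been seen, and the other tests in this part were set before their results were known.

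The treated MM.1S arrays lay further apart than those of any other group, with an SD between arrays of 0.223 against at most 0.126 elsewhere. Over the brightest 3099 of 12395 genes well above background on all arrays the SD was still 1.81 times the highest of the other groups. This ratio (95% bootstrap interval over genes 1.57 to 2.04) argues against dim signal on 1 array as the whole cause. The intervals in this paragraph come from resampling genes, which are not independent replicates, and hold no variation between arrays. After a trend on probe GC content was removed the ratio was 1.78 (1.61 to 1.83), which argues against GC content. An unequal extent of a response shared with the other lines would align the difference between the arrays with the effect there. That correlation across genes was 0.0299 (0.0139 to 0.0454), which argues against an unequal shared response as the whole cause. MM.1S effects correlated with those in RPMI-8226 and KMS-12PE at only 0.43 and 0.402, so an unequal response particular to MM.1S was not tested. An unequal response may account for a part, since the arrays lay 6.34 apart on the third component, against at most 1.20 in other groups. That component parts treated from control arrays, but the gap on it was 3.24% of the squared distance between the treated MM.1S arrays. A difference between cultures or in labelling stays open.

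Some myeloid and T cell marker genes rose in treated RPMI-8226, including CD14, CSF1R and CD2. In the lists, 6 of 10 myeloid and 3 of 9 T and NK cell members were called higher. The T and NK cell list did not pass camera with an estimated correlation (adjusted p = 0.107). Cells of another type in the treated cultures would bring their abundant transcripts, but 1 of 8 abundant monocyte genes written beforehand was called higher, S100A8, at least 2.01-fold. Of the others on the array, FCN1 and VCAN were not well above background, S100A9 was on 1 treated array, and CTSS, FCER1G and TYROBP, which control RPMI-8226 also expressed, gave 0.23, 0.06 and 0.38 without passing the test. Of 6 abundant T cell genes, CD3D rose by 1.93, CD7 and IL32 gave -0.13 and 0.23 without passing, CD3E and IL7R were not well above background, and LCK was on 1 treated array. FCN1, VCAN, CD3E and IL7R thus gave no sign of monocytes or T cells, while S100A8 and CD3D rose. LYZ was not on the array, and CTSS, FCER1G and TYROBP, already expressed in control cells, could show little of a small admixture. The counts therefore do not settle whether other cells contributed. The test was set for RPMI-8226 alone, but of the abundant T cell genes IL32 rose by 1.61 in KMS-12PE (limma adjusted p = 0.00342). LCK, well above background on 0 control arrays there, was also called higher (limma adjusted p = 0.00453). CD3D and CD7 gave 0.28 and 0.72 without passing, CD3E was on 1 control array and IL7R was not well above background. With 0 abundant monocyte genes called higher there, other cells in KMS-12PE stay open as well. Expression by the treated myeloma cells themselves is a hypothesis, and no sort that would remove other cells is named in the labels.

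TRIM49, TRIM49D1, TRIM49B and TRIM53AP fell together in KMS-12PE, as did 3 genes named after their values were seen, FRG2 by 1.69, FRG2C by 2.35 and FRG2B at least 3.29-fold, on chromosomes 4, 3 and 10, and all were well above background on no array of the other lines (0 in each). Cross-hybridisation between the TRIM paralog probes may make several probes report 1 transcript, which would not cover the FRG2 genes. The 3 FRG2 probes were not compared with each other and may likewise report 1 transcript. Between the 4 probes, 0 of 6 pairs shared a run of at least 20 identical bases, and the longest runs were 6 to 9 bases, but a probe can bind a paralog's transcript without resembling the paralog's probe, so without transcript sequences the explanation stays open. Loss of a DUX4-driven programme was set to be excluded if 0 listed DUX4-induced genes were called lower in KMS-12PE, and 0 were. Of 17 such genes on the array only HNRNPCL1 was tested there, at -0.09 (adjusted p = 0.727), so that count decides nothing.

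The remaining results here are differences in effect between lines that passed the limma test of the difference, given as the effect in the first line minus that in the second. For RPMI-8226 against MM.1S they were -4.33 for BRINP2 (adjusted p = 1.4e-05), 4.07 for CCL3 (1.4e-05), 2.24 for MARCKS (1.9e-05) and -0.43 for MYC (0.0104). For RPMI-8226 against KMS-12PE they were 2.69 for CD14 (2.42e-05), -4.08 for LHFPL2 (1.16e-05), -3.09 for SPINT2 (1.93e-05), -0.34 for IRF4 (0.0489) and -0.56 for KLF2 (0.0293). For MM.1S against KMS-12PE they were -2.63 for COBLL1 (2.47e-05), -3.20 for LHFPL2 (2.47e-05), -3.13 for SPINT2 (2.47e-05), -0.43 for IRF4 (0.018), -0.93 for KLF2 (0.00414) and -0.54 for PRDM1 (0.0244). BRINP2, CCL3, LHFPL2 and SPINT2 were not well above background in 1 group of a pair, so their fitted differences are no bounds. The IRF4 and KLF2 calls for RPMI-8226 against KMS-12PE ended under 16 and 11 of 23 settings, those of IRF4 and PRDM1 for MM.1S against KMS-12PE under 9 each, and that of MYC under 4. Under normexp the calls ended for BRINP2 (-1.12), for LHFPL2 and SPINT2 in RPMI-8226 against KMS-12PE (-1.03 and -0.78), and for LHFPL2 (-0.08), SPINT2 (-0.60) and KLF2 in MM.1S against KMS-12PE.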

How the results depend on the processing

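The 75th percentile over detected probes, and for the lists the median over detected probes and the series table, were chosen after seeing the data. Of 211 called named results among 215, 125 were called under every setting. Over all settings 4667 of 4900 comparisons of named genes kept direction and side of the threshold, 222 were no longer past it, 8 newly passed and 3 reversed. For lists these were 1461, 64, 31 and 4 of 1560. Of the 215, 75 no longer passed under normexp and 2 more reversed there, 17 no longer passed without a filter, and 71 of 2580 comparisons no longer passed when 1 array was left out. Among single settings normexp ended the most calls of named genes, and for lists the estimated correlation did, with 21. Where no cause is given, the cause was not tested.

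Under normexp 1795 genes were called in RPMI-8226, 556 in MM.1S, 181 in KMS-12PE and 2624 on the mean. Differences between lines then numbered 189 for RPMI-8226 against MM.1S, 110 for RPMI-8226 against KMS-12PE and 17 for MM.1S against KMS-12PE, and the correlations in this order of pairs were 0.505, 0.253 and 0.334. Without a filter on dim probes 2994, 3522 and 1049 genes were called in the lines, 1488, 1043 and 959 between pairs, and the correlations were 0.196, 0.132 and 0.1, with every dim probe entering the adjustment. With only the arrays of the lines compared, which leaves fewer degrees of freedom, the counts were 6679 in RPMI-8226, 2158 in MM.1S and 4658 in KMS-12PE. Between pairs they were 1935, 3338 and 992. MM.1S thus went from the most calls of the lines to the fewest. The shared spread pools its treated arrays with groups whose arrays lay closer together. A 2-fold minimum, which by construction lowers counts, gave 1223, 800, 527 and 229 in the lines and on the mean, and 766, 545 and 460 between pairs. With an estimated correlation 27 lists passed. Under fry 20 more lists passed and 1 call ended, that of histones in KMS-12PE (fry adjusted p = 0.499). Among those that newly passed, S phase genes fell in RPMI-8226 and KMS-12PE (fry adjusted p = 0.00086 and 0.00346). The list of DOT1L partners also fell in these lines (fry adjusted p = 0.000593 and 0.000977). Unlike camera, fry does not set a list against the other genes.

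Reversals under normexp were MHC class I presentation in RPMI-8226 (-0.0509), G2/M in RPMI-8226 (-0.161), NLRP13 in RPMI-8226 (0.0415) and CD14 in MM.1S (0.0457). Under quantile normalization ribosomal proteins in KMS-12PE (0.00284 relative to all genes) and MYC in MM.1S (0.0209) turned. For ribosomal proteins in MM.1S the set test turned, with adjusted p = 0.852, while the mean relative to all genes shrank to -0.00783.

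Replicate numbers did not pair the arrays, since deviations from group means correlated at 0.0292, -0.068 and 0.12 in RPMI-8226, MM.1S and KMS-12PE. With the replicate block, which uses up degrees of freedom, 3671, 4688 and 1295 genes were called in the lines, 5536 on the mean, and 1632, 679 and 588 between pairs, and 46 lists passed. Among those that did not pass with the block were the BCL2 family (adjusted p = 0.0777) and myeloid markers (adjusted p = 0.0509) in MM.1S.

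Leaving out 1 array at a time, where the lone array left is assumed to vary like the other groups, gave 3034 to 6674 genes in RPMI-8226, 4220 to 7382 in MM.1S, 1143 to 4502 in KMS-12PE and 5324 to 8020 on the mean. The range was 1755 to 5365 for RPMI-8226 against MM.1S, 772 to 2915 for RPMI-8226 against KMS-12PE and 919 to 4333 for MM.1S against KMS-12PE. Correlations ran from 0.367 to 0.43, 0.355 to 0.401 and 0.354 to 0.402, and 45 to 49 lists passed. The lowest count in RPMI-8226 and on the mean came without the second control RPMI-8226 array, and that in MM.1S without its first control array. The highest came without the second treated MM.1S array for RPMI-8226 and without the first for MM.1S and the mean. The arrays behind the other ranges of gene counts are named with the counts in the report. Slide as a block was not run because each line lies on 1 slide, and the mean of the 3 lines has no setting with fewer lines. Signal over background limits falls and rises of dim genes, which are given as bounds.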

Other observations

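The genes named in the next paragraphs, the neighbour counts without HLA genes or with a minimum distance, the shuffles matched on signal level and the tests of lists between lines were chosen after the results were seen, and the other tests in this part were set beforehand.

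In all, 43 genes rose at least 2-fold in all 3 lines, several of them named by the fixed rule, and 1 fell so. The one that fell is TNFRSF17, which encodes BCMA, a surface receptor of plasma cells, at -1.51 in RPMI-8226, -1.02 in MM.1S and -1.32 in KMS-12PE (SE 0.179, adjusted p = 0.000824, 0.00404 and 0.00311). The call of TNFRSF17 ended under normexp in MM.1S and KMS-12PE. The 43 that rose include the interferon-induced GTPase GBP4 at 3.03, 2.43 and 2.91, the amino acid oxidase IL4I1 at 3.14, 1.94 and 1.77, RGS1, a regulator of G protein signalling in lymphocytes, at 1.70, 1.53 and 1.07, and IFI6 at 1.04, 1.70 and 1.28, all well above background in every group. The interferon-induced XAF1 was at least 4.05-fold, 4.21-fold and 4.60-fold higher in the same order.

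In the chemokine receptor cluster on chromosome 3 (hg19), CCR2 and CCR3 rose in all 3 lines. CCR3, with its probe from 46307828 to 46307887, rose by 1.32, 1.49 and 1.73 in RPMI-8226, MM.1S and KMS-12PE, detected on 1 of 2 control arrays of KMS-12PE. CCR2, from 46401916 to 46401975, rose by 2.66, 1.40 and 1.34. CCR1, from 46243829 to 46243888, rose by 2.25 in KMS-12PE and gave 0.37 and -0.03 in RPMI-8226 and MM.1S (adjusted p = 0.205 and 0.933). LTF, further along the chromosome, gave -1.14 in RPMI-8226 and 1.27 in KMS-12PE, and LZTFL1 and XCR1 were not called in any line.

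A hypothesis is that raised genes are neighbours on the chromosome more often than chance. Among adjacent tested genes within 100 kb, 60 pairs in RPMI-8226, 32 in MM.1S and 23 in KMS-12PE were both raised at least 2-fold. This was 3.3, 2.39 and 4.06 times the mean of 1000 shuffles, whose highest counts were 32, 24 and 14. With HLA genes left out 54, 28 and 18 pairs stayed, and with pairs at least 5 kb apart 60, 28 and 20. Shuffles matched on signal level had means of 18.3, 12.7 and 5.38 and highest counts of 33, 25 and 15. Raised genes were thus adjacent more often than shuffled ones, which is consistent with a response shared by chromosomal regions, but genes of one family are often neighbours and answer the same signals, and this was not separated.

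For the rise of interferon-stimulated genes, a candidate explanation is transcription of interferon genes by the treated cells. It was set to be excluded if no interferon gene was called higher in at least 2 of the 3 lines, and 0 lines had one called higher. Of 17 interferon genes on the array only IFNA4 was tested in RPMI-8226 (adjusted p = 0.157, not well above background after treatment) and IFNL2 in KMS-12PE at -0.36 (adjusted p = 0.363), so transcription of interferon genes below the arrays' detection stays open.

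The mean effect over the lines was set against other splits of the arrays that swap treatment labels within lines, 100 of the 108 possible. The real split, with 6601 called genes, was the 1 split of the 100 with as many, and the highest other gave 3408. That other split mirrors KMS-12PE alone and so keeps the real groups in the other lines. The median of the others was 0 called genes in limma. Most of them mix treated and control arrays within a group, which widens the spread there. The comparison therefore mainly shows that the arrays of a group resemble each other. It cannot tell the treatment from the array's place on the slide, which follows the treatment.

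List by list, 77 differences between lines were tested after the cell cycle lists were seen to move apart. Of these 27 passed and 0 did with an estimated correlation. Outside the lists named before, the effect in RPMI-8226 lay above that in KMS-12PE by 1.11 for MHC class II genes (adjusted p = 3.14e-05, or adjusted p = 0.169 with an estimated correlation) and by 1.15 for HOXA and MEIS genes, a list that did not pass in KMS-12PE (adjusted p = 0.000114, or adjusted p = 0.0925 with an estimated correlation). MHC class I presentation differed by 0.31 between RPMI-8226 and MM.1S (adjusted p = 0.000156, or adjusted p = 0.0677 with an estimated correlation). These means include fitted values of genes below background in a group.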
